A study of Citrullus lanatus with 30 samples.

How the data were processed

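RNA from flesh of 30 watermelon fruit samples was sequenced, from 2 genotypes (wild type, WT, and clnor) at 5 ages (10, 18, 26, 34 and 42 days after pollination, DAP), with 3 libraries in each of 10 groups, as the labels group them. Per the labels' protocols, RNA was extracted with Trizol reagent, cleaned with an RNeasy mini kit with DNase I treatment, and made into libraries with an Illumina TruSeq RNA kit. Per the labels, the libraries were sequenced on a NovaSeq. Per the submitters' processing notes, TopHat2, HISAT2, StringTie and Cufflinks were used, and their versions and the genome build are not given in the sources used here. The deposited table gives TPM (transcript abundance normalized for length and depth) per gene and library for 22596 genes, with a description for each gene, unknown for 2976 of them. All 30 columns belong to the study's samples, and 0 columns to other samples.

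TPM keeps no sequencing depth, so depth per library is unknown and the precision of low values cannot be given. TPM sums of the table were 970727 to 985840 (median 981279.5) per library, and 5099 to 6433 genes were listed at 0. The most abundant gene took 18951.55 to 42491.66 TPM and the 10 most abundant genes 8.594 to 14.15% of the sum. Spearman correlations between libraries of a group were 0.9135 to 0.9831, and at most 5.01% of values of tested genes were identical in any of the 435 pairs of libraries, so no library was a copy of another.

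Values were tested as log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the 30 libraries were tested (16503), and 6093 were left out as too low. One linear model over 10 groups was fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend and robust set, 20 residual degrees of freedom) in R 4.3.3, with statmod 1.5.0 for block correlation. Contrasts were clnor against WT at each age and averaged over the ages, the change of that difference from 10 DAP to each later age with an F test over the 4 later ages, and ages against 10 DAP and against the preceding age within each genotype. Tests of these contrasts were two-sided, p-values were adjusted by Benjamini and Hochberg within each contrast, and genes with adjusted p below 0.05 were called.

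Before the table was opened, 24 gene lists were fixed as search words in gene descriptions. They were carotenoid synthesis, sugar transport, sugar metabolism, cell wall loosening, cell wall synthesis, ethylene, abscisic acid, auxin, gibberellin, chloroplast and photosynthesis, cell cycle and histones, MADS-box, NAC, AP2/ERF, WRKY, aroma and lipid volatiles, phenylpropanoid and flavonoid, cucurbitacin and triterpene, aquaporin, heat shock, ribosomal protein, seed markers, phloem markers, and epidermis and cuticle markers. Some accidental matches of the search words were removed after the descriptions were read and before any value was tested; the lists as first written were kept as an added alternative. Some inhibitors matched by the name of their target remain, such as an invertase inhibitor among the sugar metabolism genes. The search words for carotenoid synthesis also named carotenoid cleavage dioxygenases, so members of that list need not all act in synthesis. The ethylene list likewise holds genes matched by name alone, such as oxidase homologs. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, camera with a correlation estimated for each list, and fry, and adjusted over the lists of each contrast. Members were also adjusted over the list alone. Families with many similar members share reads, so single members of a family are less certain than their sum.

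Genes are named by a rule fixed before the table was opened. It takes, at each age, the 4 largest rises and 4 largest falls among called genes whose 3 clnor libraries all lie on 1 side of the 3 WT libraries (a 10% chance for 3 against 3 libraries) with a higher mean of at least 5 TPM. It also takes the 8 largest rises and falls of the averaged contrast with the same order of means at all ages, the 6 largest rises and falls of WT 34 against 10 DAP, and from each list the 4 members with the smallest p in the averaged contrast and the member with the smallest p at each age. Unnamed genes were skipped, and 177 genes resulted. Genes outside the rule are marked in the text as chosen after their values were seen.

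Ripening position was the mean over the genes changed at least 2-fold in WT from 10 to 34 DAP, each scaled to 0 at the WT 10 DAP mean and 1 at the WT 34 DAP mean and weighted by the square of its WT change. WT and clnor were compared at 18, 26 and 42 DAP by exact permutation of genotype labels within ages, two-sided. Numbers shared by chance between 2 sets of calls were computed as the product of their sizes over the genes tested.

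Alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 TPM, libraries rescaled to a common sum, upper-quartile scaling and quantile normalization, a fold change of at least 2, a fit with only the groups compared, replicate number as a fixed or random block, array weights, other list tests, other genes or ends for the ripening position, and leaving out each library in turn. Chosen after seeing the data were the lists as first written, a run without the 5 libraries nearest to another group, and a run without 26 DAP. An alternative that needs read counts was not run, since the table holds TPM. For 3 against 3 libraries all 10 splits were fitted, and for averaged and interaction contrasts 100 relabellings within ages.

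The procedure was tested on simulated data made from the 34 DAP comparison over 16503 genes. Of 100 genes raised or lowered by a log2 size of 1, 65 were called, and of 100 raised or lowered by a log2 size of 2, 98 were called. Another 12 called genes were unchanged, 6.86% of all calls. In the averaged contrast the 1 raised list was called and 0 of 19 random lists, and a position set at 0.4 was recovered as 0.41. The simulated noise was independent between genes, with the same spread of a gene in all groups. The simulation therefore does not show how the list test behaves with correlated genes, or the calls with groups of unequal spread.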

Results

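The study sequenced RNA from the fruit flesh of watermelon (Citrullus lanatus) in 30 libraries. Wild type (WT) fruits and fruits of a mutant that the labels call clnor were taken at 10, 18, 26, 34 and 42 days after pollination (DAP), with 3 libraries per genotype and age. The deposited table listed TPM (transcript abundance normalized for gene length and sequencing depth) for 22596 genes, and the 16503 genes with at least 1 TPM in at least 3 libraries were tested. Levels are given as mean TPM ± standard deviation of 3 libraries, and fold changes as log2 differences of log2(TPM + 1), a scale that understates changes of genes at low level. The labels do not say whether the replicates are separate fruits or plants, so the p-values measure the spread between these samples, which may be technical. No description in the table names a gene as NOR or non-ripening, so no gene was taken as the mutated one, and the 53 NAC genes tested are reported as a list.

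Principal component 1 (36.8% of the variance) ran along fruit age in WT, from -77.5 in a 10 DAP library to 102.2 in a 42 DAP library, and less far in clnor, from -86.5 to 12.4. Component 2 held 18.2%. Most libraries correlated best with the mean of their own group, and 5 did not. WT 18 DAP replicate 3 lay nearest to clnor 18 DAP (r 0.969, own group 0.945), and clnor 18 DAP replicate 3 lay nearest to WT 18 DAP (r 0.977, own group 0.942). At 10 DAP, clnor replicate 1 lay nearest to WT 10 DAP (r 0.972 against 0.957) and clnor replicate 3 nearest to clnor 18 DAP (r 0.969 against 0.938). The fifth was clnor 34 DAP replicate 2, nearest to clnor 42 DAP (r 0.959 against 0.951). These r values are across genes, which are not independent replicates. WT at 34 DAP had the fewest genes at 1 TPM or more (13404 to 13651, against up to 15065 in all libraries) and the lowest median level (3.925 to 4.545 TPM).

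In WT flesh 8003 genes changed from 10 to 34 DAP. Phytoene synthase (Cla97C01G008760), which makes the first carotenoid of the pathway, rose from 35.5 ± 11.2 to 281 ± 20.5 TPM (log2 2.99, limma adjusted p 1.2e-06). A 22.0 kDa class IV heat shock protein-like gene (Cla97C02G033390), a chaperone of stressed or drying tissue, rose from 0.61 ± 0.528 to 1712 ± 264 TPM, and the desiccation-related protein PCC13-62-like gene (Cla97C06G113860) from 20.9 ± 13.8 to 3308 ± 556 TPM. The cyclin-dependent kinase inhibitor SMR2 gene (Cla97C07G131760), whose product slows the cell cycle, rose from 1.08 ± 1.88 to 492 ± 203 TPM. Among the largest falls, the proline-rich protein DC2.15 gene (Cla97C08G156820) fell from 2616 ± 789 to 2.49 ± 1.32 TPM, extensin-3-like (Cla97C09G172550) from 2255 ± 205 to 3.55 ± 2.48 TPM, and an organ specific protein gene (Cla97C02G032070) from 4567 ± 1910 to 5.35 ± 1.5 TPM. A proteinase inhibitor I-B gene (Cla97C09G175800) fell from 522.5 ± 427 TPM and was listed at 0, and an aspartyl protease gene (Cla97C08G154840) fell from 461 ± 358 to 0.123 ± 0.137 TPM. 1-aminocyclopropane-1-carboxylate (ACC) oxidase (Cla97C02G043890), which makes ethylene, fell from 1192 ± 216 to 14.7 ± 5.87 TPM.

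By gene list, 3 groups moved upward as sets in WT between 10 and 34 DAP in camera with its preset correlation. Of 21 carotenoid synthesis genes 13 rose and 2 fell (14 and 4 adjusted over the list alone, median log2 1.05, camera adjusted p 3.56e-04). Of 120 heat shock and chaperone genes 59 rose and 16 fell (61 and 17 adjusted over the list alone, adjusted p 2.72e-08). Seed markers did not pass as a set (12 rose and 7 fell of 44, the same adjusted over the list alone, median -0.194, mean 0.352, camera adjusted p 0.237). Among them the 11S globulin gene (Cla97C05G092030) rose from 52.1 ± 32.9 to 1116 ± 568 TPM and a late embryogenesis abundant protein gene (Cla97C01G018900) from 59.1 ± 17.2 to 2116 ± 318 TPM. Of 76 chloroplast and photosynthesis genes 35 rose and 13 fell (37 and 14 adjusted over the list alone, adjusted p 3.56e-04). With the correlation estimated for each list the adjusted p of carotenoid, heat shock and chloroplast genes were 0.323, 0.227 and 0.501. Downward sets included the genes of cell wall loosening, which let walls extend or soften (11 rose and 70 fell of 117, 11 and 71 adjusted over the list alone, camera adjusted p 7.05e-06). Auxin genes had 10 rising and 58 falling of 102 (11 and 60 adjusted over the list alone, camera adjusted p 3.56e-04). Gibberellin genes (4 and 20 of 36, adjusted p 0.0078) and sugar transport genes (6 and 28 of 46, adjusted p 0.00863) had the same counts adjusted over the list alone. With estimated correlation the adjusted p of these 4 lists were 0.323. Phloem markers (3 rose and 18 fell of 31, 3 and 19 adjusted over the list alone) had a camera adjusted p of 0.00863, and 0.411 as adjusted p with estimated correlation. Cell cycle and histone genes also moved downward (14 rose and 53 fell of 116, 15 and 54 adjusted over the list alone, camera adjusted p 0.0218), as did cell wall synthesis genes (3 and 21 of 43, 3 and 23 adjusted over the list alone, adjusted p 0.0218). AP2/ERF transcription factor genes had 9 rising and 39 falling of 86 (9 and 40 adjusted over the list alone, camera adjusted p 0.0401). With estimated correlation the adjusted p of these 3 lists were 0.515, 0.501 and 0.501. The AP2/ERF call was lost without WT 10 DAP replicate 1 (0.087) or WT 34 DAP replicate 3 (0.0586). With the lists as first written it was lost (0.693), as was the phloem marker call (0.15), while ribosomal protein genes gained a call (0.013). Calls were also gained for aquaporins without WT 10 DAP replicate 2 (0.0332) or WT 34 DAP replicate 3 (0.0313), and for MADS-box genes without the latter (0.0365), all downward. All 11 directions were the same under each scaling tried.

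In WT, 5328 genes differed from 10 DAP at 18 DAP (2766 higher, 2562 lower), 6774 at 26 DAP (3325 and 3449), 8003 at 34 DAP (3146 and 4857) and 8405 at 42 DAP (4410 and 3995). The 18 DAP count was 3396 without WT 10 DAP replicate 1 and 2819 without WT 18 DAP replicate 2. Between successive ages, 6093 genes changed from 18 to 26 DAP, 5454 from 26 to 34 DAP (1972 higher, 3482 lower) and 619 from 34 to 42 DAP (507 higher, 112 lower). That last count depended on single libraries: it was 289, 205 and 152 without WT 34 DAP replicates 1, 2 and 3, and 197 and 110 without WT 42 DAP replicates 2 and 3. The side with more calls depended on scaling. With upper-quartile scaling it turned for 18 against 10 DAP (2417 higher, 3112 lower), 42 against 10 DAP (3761 and 4625) and 26 against 18 DAP (3359 and 3052, against 2959 and 3134 as deposited). After quantile normalization it turned for 26 against 10 DAP (3831 and 3392). After quantile normalization 55.9% of the calls for 34 against 10 DAP were higher (4475 higher, 3525 lower), against 39.3% as deposited. After quantile normalization the share was 54.5% for 34 against 26 DAP (2705 and 2258; 36.2% as deposited) and 47.9% for 42 against 34 DAP (81 and 88; 81.9% as deposited). Upper-quartile scaling gave 57.4% for 42 against 34 DAP (232 higher, 172 lower). The median log2 change of all genes tested for 34 against 10 DAP was -0.131 as deposited and 0.0767 after quantile normalization; for 34 against 26 DAP it was -0.13 and 0.021, and for 42 against 34 DAP 0.147 and 0.00312.

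At 10 DAP clnor flesh differed from WT in few genes. A gibberellin-regulated protein gene (Cla97C01G016400), of a family that marks growth responses, was at 12.9 ± 7.7 TPM in clnor and 0.32 ± 0.554 TPM in WT (log2 3.33, adjusted p 0.014). The oil body-associated protein 1A-like gene (Cla97C09G172070), of lipid storage, was at 40.9 ± 16 against 5.95 ± 2.54 TPM. Lower in clnor were the pyruvate decarboxylase 2-like gene (Cla97C10G205630), the entry to ethanol fermentation (49.7 ± 25.1 against 436 ± 140 TPM, log2 -3.16), and a carboxypeptidase gene (Cla97C07G143300, 7.78 ± 9.3 against 58.9 ± 37.6 TPM). So were a pectin methylesterase inhibitor-like gene (Cla97C05G089170, 4.16 ± 2.97 against 40.3 ± 22 TPM) and an aquaporin gene (Cla97C10G203070, 47.4 ± 63.1 against 174 ± 22.5 TPM), which carries water across membranes. The NAC gene Cla97C10G190580, of a transcription factor family that includes ripening regulators, was already lower (76 ± 25 against 208 ± 53.9 TPM, log2 -1.46, adjusted p 0.014).

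Across all genes 78 passed at 10 DAP, 41 higher and 37 lower in clnor (45 and 50 with upper-quartile scaling). With a fit of the 2 groups alone 0 passed, with a pseudocount of 0.1 31 and after quantile normalization 154. The count fell to 50, 17 and 38 without WT 10 DAP replicates 1, 2 and 3 and to 13 without clnor 10 DAP replicate 2, and was 309 without clnor 10 DAP replicate 1. As sets, the 191 ribosomal protein genes, of protein synthesis, lay higher in clnor (median log2 0.237, camera adjusted p 1.59e-12) with no member passing singly, also adjusted over the list alone. The 43 cell wall synthesis genes lay lower (median -0.269, adjusted p 7e-04), again with no member passing. Cell cycle and histone genes lay higher (3 higher and 0 lower of 116, 10 and 2 adjusted over the list alone, median 0.108, adjusted p 0.0146). That call was lost without WT 10 DAP replicate 3 (0.0825) or clnor 10 DAP replicate 2 (0.092). Calls downward were gained for phloem markers without WT replicate 2 (0.0458), sugar transport without WT replicate 3 (0.0441), WRKY without clnor replicate 1 (0.0264) and cell wall loosening without clnor replicate 3 (0.02). With estimated correlation the adjusted p was 0.821 for each of these 3 lists.

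At 18 DAP the genes that set clnor apart included some at high level in WT. A nodulin-like gene of the major facilitator transporters (Cla97C02G031010) was at 4232 ± 2880 TPM in WT and 573 ± 947 TPM in clnor (log2 -5.22, adjusted p 0.022), and an organ-specific protein P4-like gene (Cla97C11G211230) at 140 ± 176 and 6.64 ± 10.9 TPM. The root meristem growth factor 9-like gene (Cla97C02G027310), a peptide signal of dividing tissue, was at 36.8 ± 16.9 TPM in WT and 0.577 ± 0.999 TPM in clnor, where it was listed at 0 from 26 DAP on. Higher in clnor were a cytochrome P450 gene (Cla97C05G101010, 66.8 ± 47.5 against 4.49 ± 4.04 TPM) and a peroxidase gene (Cla97C03G055890, 204 ± 152 against 14.8 ± 11.2 TPM), an enzyme of cell wall cross-linking. In libraries of the youngest age phytoene synthase was at 25.75, 14.29 and 13.99 TPM in clnor and 26.14, 32.46 and 47.9 TPM in WT. The nearest values of the genotypes, 25.75 and 26.14 TPM, almost touched, so no difference is claimed at that age. The gene was not among those that passed at every age. At 18 DAP phytoene synthase was at 47.9 ± 42.4 TPM in clnor and 154 ± 68.2 TPM in WT (log2 -1.91, adjusted p 0.013). The clnor means at this age mix 2 kinds of values, since replicate 3, the clnor library nearest to WT, stood apart. In replicates 1, 2 and 3 the nodulin-like gene (Cla97C02G031010) was at 11.66, 40.95 and 1665.9 TPM, the peroxidase gene (Cla97C03G055890) at 251.22, 327.13 and 34.39 TPM, and phytoene synthase (Cla97C01G008760) at 21.81, 24.97 and 96.81 TPM.

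The 18 DAP comparison called 387 genes, 227 higher and 160 lower, and rested on which libraries were used. With a fit of the 2 groups alone it called 0. It called 18 genes without WT 18 DAP replicate 2, 9 and 15 without clnor 18 DAP replicates 1 and 2, 1661 without WT 18 DAP replicate 3 and 2196 without clnor 18 DAP replicate 3, the libraries nearest to the other genotype. Replicates lay further apart in ripening position at 18 DAP than at other ages. Its standard deviation was 0.24 in WT and 0.156 in clnor, against 0.0274 and 0.0337 at 26 DAP. The fit over 10 groups uses 1 spread per gene for all groups, so p-values at 18 DAP may be too small. The share called higher was 58.7% as deposited and 39.7% after quantile normalization (154 higher, 234 lower). Sets higher in clnor were cell wall loosening (5 higher and 2 lower of 117, 15 and 5 adjusted over the list alone, median log2 0.533, camera adjusted p 0.0278) and AP2/ERF (3 and 1 of 86, 9 and 1 adjusted over the list alone, median 0.331, adjusted p 0.0278). Phloem markers were also higher as a set (0 and 0 of 31, 4 and 0 adjusted over the list alone, median 0.316, adjusted p 0.0444). With estimated correlation each adjusted p was 0.827. The loosening call was lost without WT 18 DAP replicate 1 (0.0613), WT replicate 2 (0.255) or clnor replicate 2 (0.223), and the AP2/ERF call without WT replicate 1 (0.361) or 2 (0.0713). The phloem call was lost without WT replicates 1 (0.26) or 2 (0.234) or clnor replicates 2 (0.208) or 3 (0.119). With the lists as first written, AP2/ERF (0.497) and phloem markers (0.361) did not pass. Ribosomal protein genes gained an upward call without WT replicate 2 (1.01e-05) or clnor replicates 2 (0.0132) or 3 (0.00242). Chloroplast genes gained an upward call without WT replicate 3 (0.000661), and heat shock genes a downward call without clnor replicate 3 (0.0431).

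At 26 DAP some genes near 0 in WT were at clear levels in clnor. A beta-glucosidase 12-like gene (Cla97C03G063890) was at 128 ± 73.9 TPM in clnor and 0.08 ± 0.106 TPM in WT. Arogenate dehydratase (Cla97C02G047990), of phenylalanine synthesis, was at 121 ± 74.3 and 1.09 ± 0.236 TPM (log2 5.58, adjusted p 2.1e-06), and a no apical meristem (NAM) protein gene (Cla97C03G063540) at 64.7 ± 35.9 TPM in clnor while listed at 0 in WT. The other way, mannan endo-1,4-beta-mannosidase 1-like (Cla97C08G145130), which cleaves wall mannans, was at 472 ± 30.5 TPM in WT and 1.64 ± 0.707 TPM in clnor (log2 -7.52). The 11S globulin seed storage protein 2-like gene (Cla97C05G092030) was at 629 ± 550 and 0.92 ± 0.19 TPM, and an endoglucanase gene (Cla97C11G210630), of wall softening, at 26.2 ± 5.07 and 0.637 ± 0.376 TPM. The small chain of ribulose bisphosphate carboxylase (Cla97C05G104530), the enzyme of carbon fixation, was at 1485 ± 536 in WT and 145 ± 42.9 TPM in clnor.

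Of all genes tested 2552 passed at 26 DAP, 1595 higher and 957 lower in clnor. Without WT 26 DAP replicate 2 the count was 1488 and without clnor 26 DAP replicate 1 it was 1682. After quantile normalization 48.3% of calls were higher (1279 higher, 1368 lower), against 62.5% as deposited. The median log2 difference of all genes was 0.104 with libraries rescaled to a common sum and 0 after quantile normalization. Of 46 sugar transport genes 11 were called higher and 1 lower (the same adjusted over the list alone), and of 102 auxin genes 17 and 7 (17 and 8 adjusted over the list alone). More were called higher than lower under each scaling tried. The other members did not pass, and no list passed camera. Chloroplast genes (5 higher, 10 lower of 76, list alone 6 and 10) and heat shock genes (4 and 7 of 120, list alone 4 and 6) came closest, each with adjusted p 0.0814 and lower in clnor. Without clnor 26 DAP replicate 2 both passed (0.000321 and 0.0196).

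At 34 DAP more genes differed between the genotypes than at any other age. Phytoene synthase was at 281 ± 20.5 TPM in WT and 28.5 ± 3.16 TPM in clnor (log2 -3.26, adjusted p 6.7e-07). Beta-carotene hydroxylase (Cla97C05G090480) was at 1506 ± 97.2 and 335 ± 44.8 TPM, and alkaline alpha-galactosidase (Cla97C04G070460), which frees sugar from transported raffinose sugars, at 2878 ± 460 and 784 ± 143 TPM. Gibberellin 20-oxidase (Cla97C05G089570), of gibberellin synthesis, was at 2105 ± 189 TPM in WT and 11.8 ± 13.9 TPM in clnor (log2 -7.94, adjusted p 4.3e-07). SMR2 was at 492 ± 203 and 2.43 ± 2.11 TPM, and a phosphate transporter gene (Cla97C10G205070) at 482 ± 162 and 2.93 ± 0.209 TPM. Higher in clnor were the abscisic stress ripening-like gene (Cla97C08G146170, 1949 ± 757 against 21.8 ± 14 TPM, log2 6.53) and the nitrate transporter family gene NRT1/PTR 4.6 (Cla97C05G106700, 140 ± 33.2 against 0.813 ± 0.544 TPM). ACC oxidase was higher too (314 ± 103 against 14.7 ± 5.87 TPM), as was a 9-cis-epoxycarotenoid dioxygenase gene of abscisic acid synthesis (Cla97C07G137780, 72.7 ± 14.7 against 1.85 ± 0.226 TPM).

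**Figure D1:**
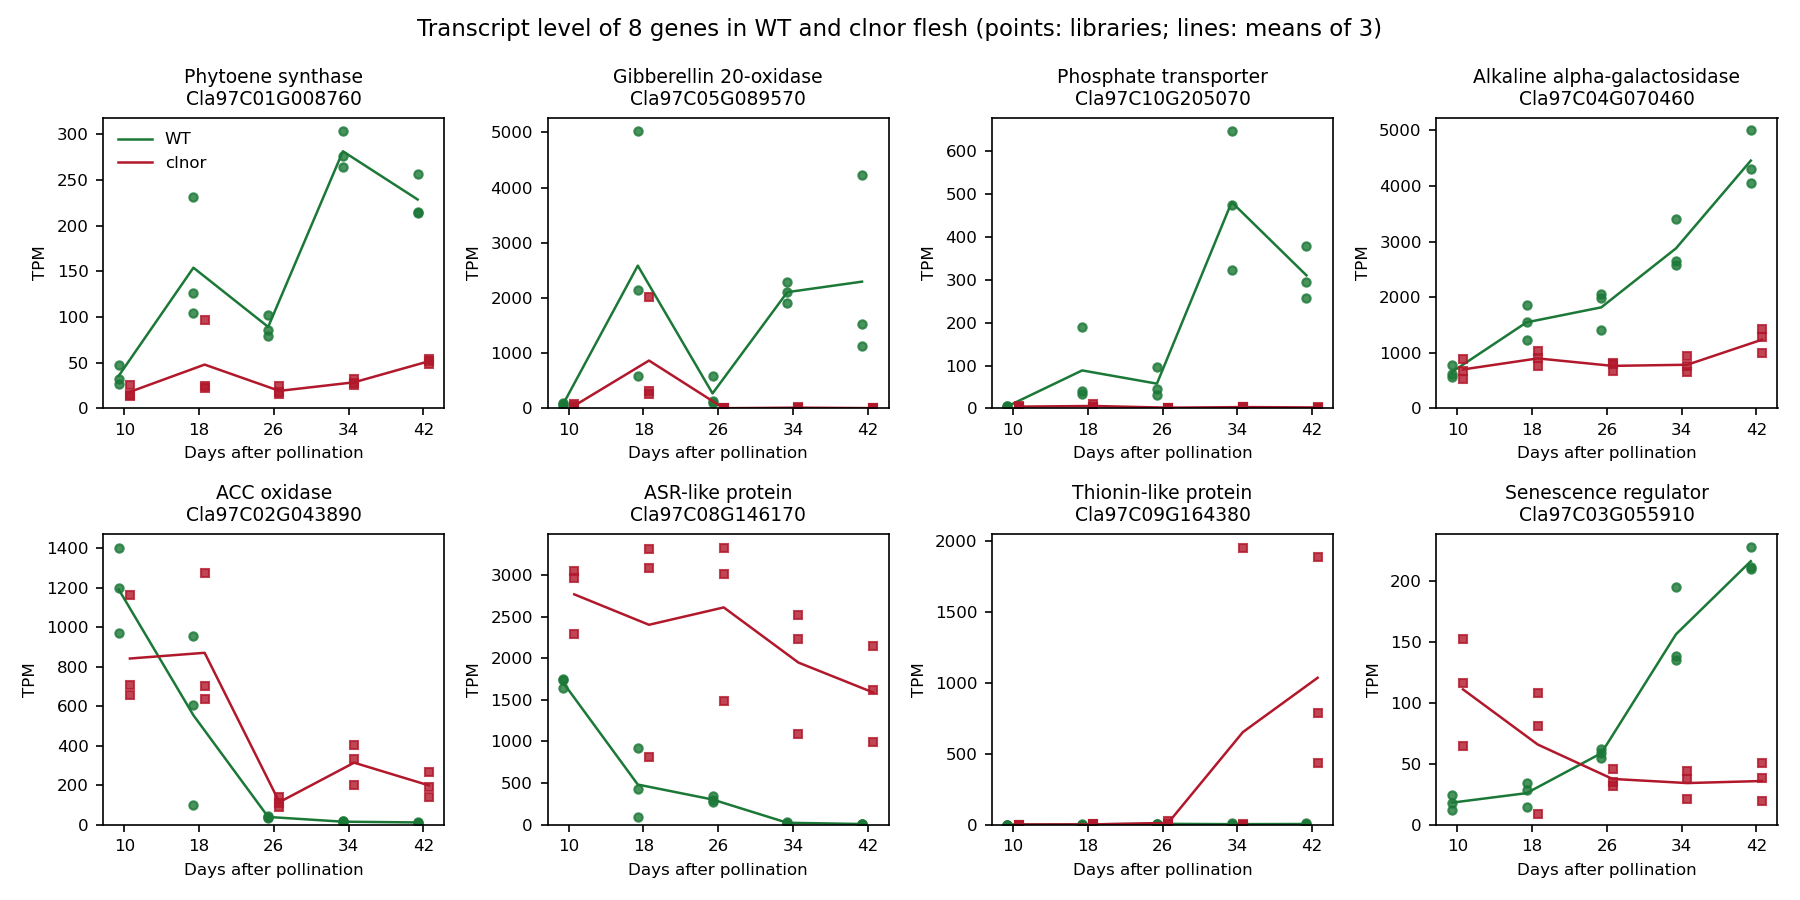
Levels of 8 genes (TPM, y axis) against age (DAP, x axis) in WT (green circles) and clnor (red squares), with 1 point per library and lines through the means of 3. Phytoene synthase reaches a mean of 281 TPM in WT and 28.5 TPM in clnor at 34 DAP, while the abscisic stress ripening-like gene stays at 1949 TPM in clnor and is at 21.8 TPM in WT.

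In total 6507 genes passed at 34 DAP, 4518 higher and 1989 lower in clnor. This split depended on the scaling: 69.4% were higher as deposited and 49.1% after quantile normalization (2874 higher, 2975 lower). The median log2 difference of all genes tested was 0.199 as deposited, 0.211 with libraries rescaled to a common sum, 0.121 with upper-quartile scaling and -0.00972 after quantile normalization. Among called members, more were higher than lower under every scaling for sugar transport (22 higher, 7 lower of 46, list alone 23 and 7) and auxin genes (34 and 10 of 102, list alone 35 and 10). The same held for MADS-box (11 and 2 of 30, list alone 12 and 2), WRKY (16 and 5 of 48, list alone 16 and 6) and phloem marker genes (10 and 1 of 31, the same over the list alone). More phenylpropanoid and flavonoid genes were called lower than higher under every scaling (12 higher, 18 lower of 72, the same over the list alone), with a median of 0.00315 and a mean of -0.165. Caffeoyl-CoA 3-O-methyltransferase (Cla97C11G219650), of lignin precursors, was at 102 ± 40 TPM in clnor and 1033 ± 197 TPM in WT. Cell cycle genes had 27 called higher and 15 lower of 116 (the same over the list alone), and 17 and 21 after quantile normalization. No list passed camera, the closest being heat shock genes (20 higher, 26 lower of 120, the same over the list alone, adjusted p 0.0724, lower in clnor), which passed without clnor 34 DAP replicate 1 (0.0243).

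At 42 DAP clnor still lacked several late WT transcripts. The cryptdin protein-like gene (Cla97C09G162230) was at 494 ± 356 TPM in WT and listed at 0 in all clnor groups, and an inhibitor I family gene (Cla97C06G122340) at 233 ± 180 TPM in WT was listed at 0 in clnor. Gibberellin 20-oxidase was at 2296 ± 1690 TPM in WT and 3.25 ± 1.23 TPM in clnor (log2 -8.88). Alkaline alpha-galactosidase was at 4454 ± 495 and 1235 ± 212 TPM, and phytoene synthase at 228 ± 24.3 and 51.5 ± 2.26 TPM. A thionin-like protein 2 gene (Cla97C09G164380), of plant defence, was at 1037 ± 758 TPM in clnor and 4.12 ± 6.3 TPM in WT (log2 8.18, adjusted p 0.00051). The 18 kDa seed maturation protein gene (Cla97C04G069720) was at 240 ± 75.6 and 1.43 ± 1.36 TPM, and the terpene synthase 10-like gene (Cla97C02G027120) at 261 ± 69 and 16.4 ± 10.7 TPM. The 42 DAP comparison called 5381 genes, 3105 higher and 2276 lower (57.7% higher as deposited; 46.4% after quantile normalization, 2541 and 2930). Of 29 ethylene genes 12 were called higher and 1 lower (12 and 3 adjusted over the list alone, 9 and 2 after quantile normalization), among them the ACC oxidase homolog Cla97C06G116470 (66.3 ± 19.7 against 0.78 ± 0.538 TPM). That homolog entered the list by its name, which does not show a role in ethylene synthesis. Of 116 cell cycle genes 15 were called higher and 28 lower (15 and 30 adjusted over the list alone), with more lower under every scaling, for example a cyclin-C1-1-like gene (Cla97C02G026230, 30.5 ± 2.88 against 77.3 ± 19.8 TPM). No list passed camera, but ribosomal protein genes passed upward without clnor 42 DAP replicate 3 (0.0371).

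**Figure D2:**
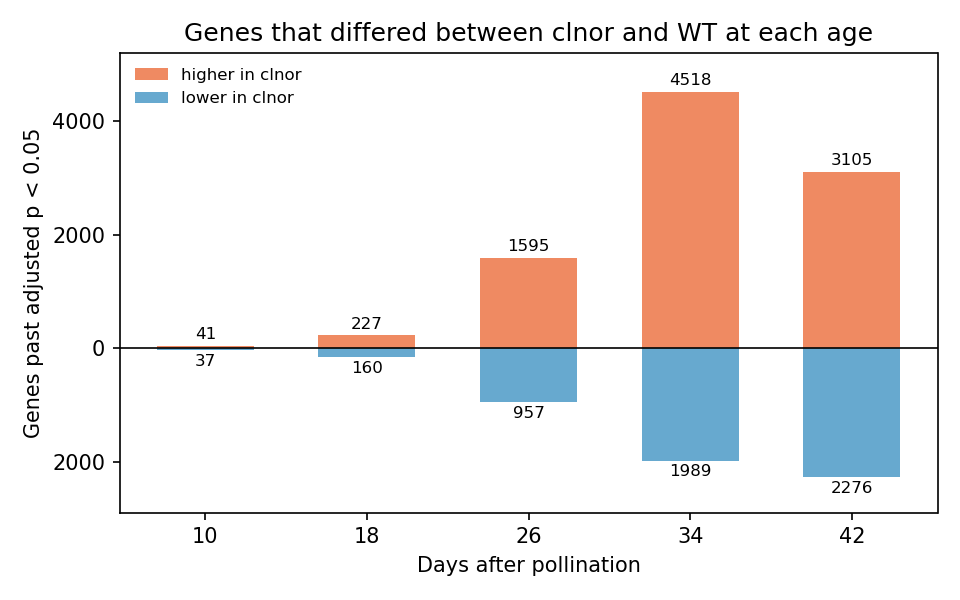
Genes called between clnor and WT (y axis, number of genes) at each age (x axis, DAP), with bars upward for genes higher and downward for genes lower in clnor. The count goes from 78 at 10 DAP to 6507 at 34 DAP and 5381 at 42 DAP.

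Averaged over the 5 ages, 7958 genes differed, 5245 higher and 2713 lower in clnor (65.9% higher as deposited; 47.6% after quantile normalization, 3693 and 4072). The largest rises with the same order of means at every age included the abscisic stress ripening-like gene (log2 4.13), the 18 kDa seed maturation protein gene (4.11), a pathogen induced 4 protein gene (Cla97C06G116580, 4.21) and cellulose synthase-like protein H1 (Cla97C02G035460, 3.70), which builds wall glucans. The largest falls included the 11S globulin gene (-6.36), the nodulin-like transporter gene (-5.62), the organ-specific P4-like gene (-5.10), gibberellin 20-oxidase (-5.08) and a senescence regulator gene (Cla97C10G203490, -4.00). In all, 2685 called genes had the clnor mean above the WT mean at all 5 ages and 1165 below it. Only 7 genes passed at each of the 5 ages, 6 of them in a constant direction, and those outside the naming rule are named here after their values were seen. The 1 gene higher throughout was that of argonaute 10 (Cla97C05G085880), which binds small RNAs. The 5 lower throughout were pyruvate decarboxylase 2-like, the NAC gene Cla97C10G190580, a serine/threonine protein kinase 1 gene (Cla97C06G113640), a dehydrogenase/reductase gene (Cla97C05G095170) and a shikimate dehydrogenase-like gene (Cla97C02G027300). The other, a pyruvate, phosphate dikinase regulatory protein gene (Cla97C03G056170), was lower in clnor at 10 DAP and higher at the later ages. Calls were shared between neighbouring late ages: 2397 genes were higher at both 34 and 42 DAP (850 by chance) and 1327 lower at both (274 by chance), with 11 in opposite directions. Between 10 and 34 DAP, 9 were higher at both (11.2 by chance) and 9 lower at both (4.46), with 10 opposite.

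Carotenoid synthesis genes split in the averaged comparison (7 higher, 6 lower of 21; 8 and 6 adjusted over the list alone; 4 and 6 after quantile normalization, 7 and 7 with upper-quartile scaling). Zeaxanthin epoxidase (Cla97C08G156320, log2 -1.07), phytoene synthase (-2.09), beta-carotene hydroxylase (-1.34) and lycopene beta/epsilon cyclase (Cla97C02G028550, -0.97) were all lower. Their list median was 0.0491 and its mean -0.136, with camera downward (adjusted p 0.387). Sugar transport genes (20 higher, 10 lower of 46, list alone 21 and 10), which move sugars across membranes, had more called higher than lower, such as sugar transporter ERD6-like 7 (Cla97C07G128370, 1.48) and polyol transporter 5-like (Cla97C02G032200, 1.61). Sugar metabolism genes (18 and 13 of 48, list alone 19 and 13, 14 and 14 after quantile normalization) held a lower alkaline alpha-galactosidase (-1.13) and a higher invertase inhibitor (Cla97C06G110110, 2.05). Of cell wall loosening genes 43 were higher and 19 lower of 117, the same adjusted over the list alone, with endoglucanase (-2.85) and pectate lyase (Cla97C05G106630, -1.55) among the lower. Cell wall synthesis genes (9 and 5 of 43, the same over the list alone) turned to 7 and 11 after quantile normalization, and their median (0.0122) and mean (0.12) were positive while camera pointed downward.

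In 4 hormone lists more members were called higher than lower in clnor under each scaling, and none of these lists passed camera. Ethylene had 12 higher and 5 lower of 29, abscisic acid 10 and 5 of 25, gibberellin 19 and 6 of 36 (each the same adjusted over the list alone) and auxin 42 and 14 of 102 (43 and 14 adjusted over the list alone). Examples were an ethylene receptor gene (Cla97C11G217310, log2 0.69), the abscisic acid receptor PYL8-like gene (Cla97C01G000570, 0.97), the gibberellin receptor GID1A gene (Cla97C03G066940, 0.96) and an auxin efflux carrier gene (Cla97C10G184680, 2.14). An auxin transporter-like protein 2 gene (Cla97C02G031020, -1.88) and a DELLA protein gene (Cla97C09G167510, -0.83), a brake on gibberellin responses, were lower. Among transcription factors, MADS-box (12 and 5 of 30), NAC (18 and 5 of 53), WRKY (19 and 6 of 48, each the same over the list alone) and AP2/ERF genes (43 and 9 of 86, list alone 45 and 9) had more called higher than lower under each scaling. Agamous-like MADS-box protein A (Cla97C10G201170, 2.41), which acts in fruit and seed development, and WRKY transcription factor 11 (Cla97C10G188410, 1.23) were higher. The NAC genes Cla97C06G125640 (-2.37), Cla97C10G190580 (-1.78) and NAC 73-like (Cla97C03G059250, -1.03) and the ethylene responsive transcription factor 2a gene (Cla97C09G163370, -0.75) were lower.

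The other lists went both ways or depended on scaling. Chloroplast and photosynthesis genes had 22 higher and 13 lower of 76 (19 and 19 after quantile normalization; median -0.0701, mean 0.0287, camera downward), with chlorophyllase-2 (Cla97C06G115980, 1.55), of chlorophyll breakdown, higher. Cell cycle and histone genes had 39 and 16 of 116 (27 and 27 after quantile normalization). Aroma and lipid volatile genes had 9 and 7 of 29 (11 and 9 over the list alone, 7 and 9 after quantile normalization, 8 and 9 with upper-quartile scaling). Aroma genes had a positive median (0.0403) and mean (0.0923) with camera downward. Phenylpropanoid and flavonoid genes had 18 and 15 of 72 (10 and 19 after quantile normalization, 15 and 16 with upper-quartile scaling), with a median of 0.0341 and a mean of -0.0208. Heat shock genes had 27 and 27 of 120 (27 and 26 over the list alone, 22 and 36 after quantile normalization, 26 and 33 with upper-quartile scaling), with a median of 0.00935, a mean of 0.00829 and camera downward. Epidermis and cuticle markers had 17 and 16 of 46 (17 and 17 over the list alone, 9 and 18 after quantile normalization), with a median of 0.151 and a mean of -0.0294. More ribosomal protein genes were called higher than lower under each scaling (67 and 12 of 191, list alone 65 and 12), as for phloem markers (10 and 1 of 31, list alone 9 and 1) and aquaporins (7 and 4 of 25, whose median went from 0.109 to -0.00465 after quantile normalization). More seed markers were called lower than higher (2 and 8 of 44), such as a late embryogenesis abundant protein gene (Cla97C01G018900, -1.36), and cucurbitacin genes had 1 and 1 of 5 (1 and 2 after quantile normalization). None of the 24 lists passed camera averaged over ages, with adjusted p from 0.342 for seed markers to 0.925.

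The genotype difference changed with age for many genes. Relative to the difference at 10 DAP, 5 genes had another difference at 18 DAP, 665 at 26 DAP, 3951 at 34 DAP and 3223 at 42 DAP, and 3805 passed a test over the 4 later ages together. The 5 at 18 DAP, named after their values were seen, were the root meristem growth factor 9-like gene (change of difference -4.67), the pectin methylesterase inhibitor-like gene (3.57), and genes of a pyruvate, phosphate dikinase regulatory protein (Cla97C03G056170, 1.51), CST complex subunit CTC1 (Cla97C05G101180, -1.56) and a tetratricopeptide repeat-like protein (Cla97C05G107930, 2.13). The 34 DAP difference of gibberellin 20-oxidase (log2 -7.94, against -0.89 at 10 DAP) and of the abscisic stress ripening-like gene (6.53, against 0.69) are examples. The 18 DAP count was 3 without WT 18 DAP replicate 2 or clnor 18 DAP replicate 2, 25 without WT 18 DAP replicate 3, 8 and 13 without clnor 10 DAP replicates 2 and 3, and 22 and 266 without clnor 18 DAP replicates 1 and 3. The 26 DAP count was 412 and 365 without WT 10 DAP replicates 1 and 2, 340 and 330 without WT 26 DAP replicates 1 and 2, and 343 and 436 without clnor 26 DAP replicates 1 and 2.

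Within clnor genes also changed with age. From 10 to 34 DAP carotenoid genes rose as a set (9 rose, 1 fell of 21, 10 and 1 adjusted over the list alone, camera adjusted p 7.66e-04). So did heat shock genes (43 and 4 of 120, 49 and 7 adjusted over the list alone, adjusted p 6.17e-07) and chloroplast genes (25 and 2 of 76, 28 and 2 adjusted over the list alone, adjusted p 2.01e-04). With estimated correlation the adjusted p of these 3 lists were 0.238, 0.221 and 0.465. Cell wall loosening genes fell as a set (1 rose, 47 fell of 117, list alone 3 and 51, adjusted p 5.06e-10), with an adjusted p of 0.221 at estimated correlation. Phytoene synthase was at 18 ± 6.7 TPM at 10 DAP and 28.5 ± 3.16 TPM at 34 DAP in clnor. Against 10 DAP, 1168 genes differed in clnor at 18 DAP (677 higher, 491 lower), 5748 at 26 DAP, 3995 at 34 DAP and 6441 at 42 DAP. Upper-quartile scaling turned the 18 DAP split to 599 higher and 690 lower (46.5% higher; 58% as deposited). Between successive ages, 5196 genes changed from 18 to 26 DAP, 2612 from 26 to 34 DAP and 338 from 34 to 42 DAP (58.9% higher as deposited; 46% with upper-quartile scaling, 190 and 223).

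Several clnor counts depended on single libraries. The 18 against 10 DAP count was 197, 100 and 3455 without clnor 10 DAP replicates 1, 2 and 3, and 247 without clnor 18 DAP replicate 3. The 34 against 26 DAP count was 1328 without clnor 26 DAP replicate 1 and 1586 without clnor 34 DAP replicate 3. The 42 against 34 DAP count was 183, 724 and 27 without clnor 34 DAP replicates 1, 2 and 3, and 74, 511 and 64 without clnor 42 DAP replicates 1, 2 and 3.

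Of genes that rise as WT flesh ripens, 3.75, 18.3 and 40.9% were called lower in clnor at 18, 26 and 42 DAP, and of those that fall 3.81, 20.2 and 40.7% were called higher. Of the 3146 genes that rose and 4857 that fell in WT from 10 to 34 DAP, 1286 rising genes were lower in clnor at 42 DAP (433.9 by chance) and 1977 falling genes were higher (913.8 by chance), while 158 and 83 went the same way. Of these calls at 42 DAP 93.1% were opposite to the WT course. At 26 DAP the counts were 577 and 980 (182.4 and 469.4 by chance; 90.5% opposite) and at 18 DAP 118 and 185 (30.5 and 66.81 by chance; 98.1% opposite). The means of the 18, 26 and 42 DAP libraries took no part in defining the course. Those libraries did enter the filter and the spread of each gene, which used all 30 libraries.

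A ripening position was computed for each library from the 4466 genes that changed at least 2-fold in WT from 10 to 34 DAP (1444 rising, 3022 falling), with 0 at the WT 10 DAP mean and 1 at the WT 34 DAP mean. WT libraries lay at 0.483 ± 0.24 at 18 DAP, 0.64 ± 0.0274 at 26 DAP and 0.948 ± 0.0444 at 42 DAP. The clnor libraries lay at 0.0291 ± 0.0362, 0.202 ± 0.156, 0.318 ± 0.0337, 0.374 ± 0.0348 and 0.485 ± 0.0425 from 10 to 42 DAP. Over 18, 26 and 42 DAP clnor lay 0.355 lower than WT (difference -0.355; two-sided exact permutation within ages over 8000 relabellings, p 5e-04). At single ages the differences were -0.281 (p 0.2), -0.322 (p 0.1) and -0.462 (p 0.1) in exact permutation tests of 20 relabellings, where the smallest possible p is 0.1. Leaving out single libraries moved the difference between -0.388 and -0.31.

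**Figure D3:**
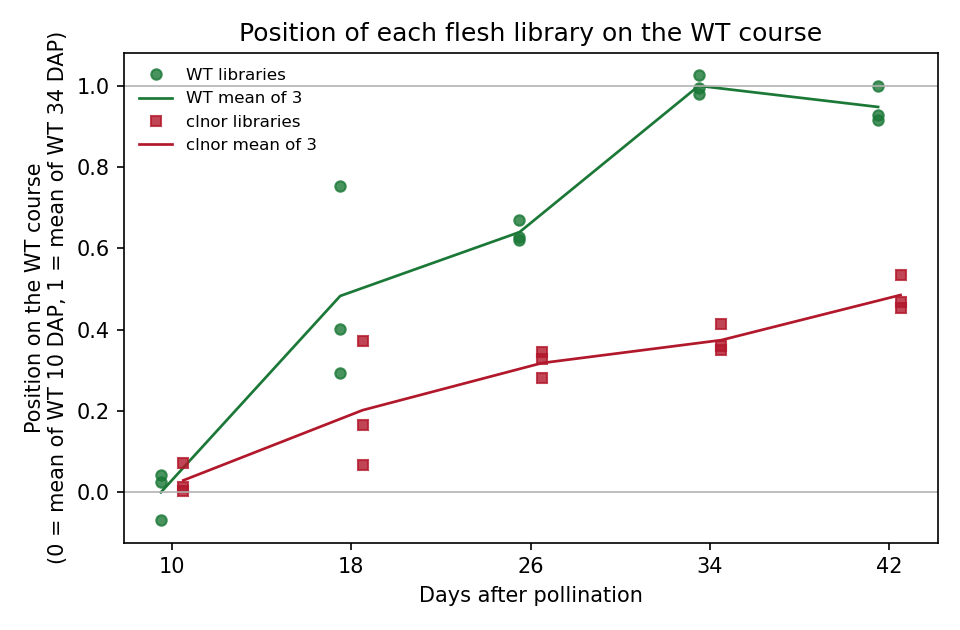
Ripening position (y axis, 0 at the mean of WT at 10 DAP and 1 at the mean of WT at 34 DAP) against age (x axis, DAP) for WT (green circles) and clnor (red squares), with 1 point per library and lines through the means of 3. WT lies at 0.948 at 42 DAP and clnor at 0.485.

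By correlation with WT means over all genes tested, clnor libraries matched WT of the same age at 10 and 26 DAP, and 10 or 18 DAP at 18 DAP (18, 10 and 18 for replicates 1, 2 and 3). At 34 DAP they matched WT of 18, 10 and 10 DAP, and at 42 DAP all 3 matched WT of 26 DAP. With the position genes only, clnor 18 DAP replicate 1 matched WT of 10 DAP and clnor 34 DAP replicate 2 WT of 26 DAP, and the other libraries matched the same ages.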

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

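In this part the tests of a shared ripening stage at 26 DAP, of a wrong label on clnor 18 DAP replicate 3 alone over 283 genes, and of all regroupings of libraries were chosen after the results were seen. The test over genotype genes unchanged with age was added last, with its rule written before its values.

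The genotype difference changed with age, and an interaction test between the ages called 5 genes at 18 DAP, 665 at 26 DAP, 3951 at 34 DAP and 3223 at 42 DAP against the difference at 10 DAP, and 3805 over the 4 later ages. Among the 177 named genes the difference varied with age for 132. For 6 of them it passed in opposite directions at different ages. The senescence regulator gene Cla97C03G055910 was higher in clnor at 10 DAP (log2 2.52) and lower at 34 and 42 DAP (-2.21 and -2.67), and an abscisic acid receptor gene (Cla97C11G212910) went from 1.17 at 10 DAP to -0.94 and -1.21. The pectin methylesterase inhibitor-like gene Cla97C05G089170 (-3.01 at 10 DAP, 1.26 at 34 DAP), the xyloglucan endotransglucosylase gene Cla97C05G107400 (-2.98 at 10 DAP, 1.75 at 42 DAP), a sugar transporter gene (Cla97C07G139970; -1.08 at 26 DAP, 0.78 at 34 DAP) and an ethylene-responsive transcription factor gene (Cla97C04G071960; -1.82 at 10 DAP, 1.21 at 34 DAP) went the other way. Over all genes tested, 90 passed in opposite directions at different ages.

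Flesh of clnor lay earlier than WT flesh of the same age on the WT course. Scaling and composition of the deposited values would have to remove the gap when all libraries are given the same distribution, but after quantile normalization clnor still lay at -0.443 relative to WT at 42 DAP, with standard deviations of 0.0337 and 0.037 in the groups. A delay along the WT course alone would place every clnor level within the range that WT passes through. At 42 DAP 4.41% of the genes tested lay outside WT at all 5 ages, 541 above and 186 below. WT levels between the sampled ages are unknown, so a delay alone is not excluded by this share. What sets these genes apart from the sampled WT ages was not tested.

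At 26 DAP 592 genes peaked in clnor and WT alike (92.9 by chance), and others dipped. Scaling is argued against by the 574 shared peaks after quantile normalization (75.5 by chance). A stage of the WT ripening course, time of day or harvest conditions of the 26 DAP libraries, and fruit age itself cannot be told apart. For a stage, clnor lay at an earlier position than WT at 26 DAP (0.318 against 0.64). Yet all 3 clnor libraries of 26 DAP, like those of 42 DAP, correlated best with WT of 26 DAP. That correlation takes in the shared peak and dip genes, so for the 26 DAP libraries it partly restates the pattern. In clnor at 42 DAP the shared peak genes had a mean log2 level of 4.34 ± 0.331, between 3.67 ± 0.134 at 34 DAP and 5.2 ± 0.331 at 26 DAP, which settles neither. For time of day, 3 of 20 genes with a clock name (15%) peaked or dipped there in both genotypes against 5.13% of other genes (one-sided Fisher's exact p 0.0804). The clock list was chosen after values were seen. A peak or dip also rests on the step from 18 DAP, where 40% of clock genes stood apart in both genotypes, against 1.39% of others. The share therefore does not single out 26 DAP, and its p is descriptive only. The labels give no hour of harvest.

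At 18 DAP, WT replicate 3 lay nearest to the clnor mean and clnor replicate 3 nearest to the WT mean. For a test, 283 genes were taken whose clnor and WT libraries lay apart without overlap at all 4 other ages (0.206 by chance). WT replicate 3 had 36.4% of them on the clnor side, nearer to WT replicates 1 and 2 (25.4 and 15.5%) than to clnor replicates 1 and 2 (81.6 and 83%). Clnor replicate 3, at 40.3%, stood close to WT replicate 3. With or without an exchange of labels 1 clnor library would have a low share, so these shares cannot decide on an exchange. The rule written before the test asked for most genes on the wrong side in both replicate 3 libraries for an exchange, and on the own side in both against it. Only clnor replicate 3 had most on the wrong side, so that rule left the exchange open. A reading against it from WT replicate 3 alone was chosen after its value was seen, and is not drawn because clnor replicate 3 stood nearly as low. Clnor replicate 3 had 40.3% on the clnor side, so a wrong genotype label on that library alone and a true clnor library cannot be told apart. Fruits of different ripening position within 18 DAP also stay open. The positions of WT replicate 3 (0.294) and clnor replicate 3 (0.373), between the other clnor and WT libraries, follow largely from how these libraries were picked. Genotype genes unchanged with age would keep to the side of the label if only position differed, but there were 17, fewer than the 20 asked for. Of these 29.4% lay on the clnor side in clnor replicate 3 and also in WT replicate 3, against 94.1 and 82.4% in clnor replicates 1 and 2, too few genes to decide on position or on a wrong label.

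For groups of 3 against 3 libraries the 10 splits are too few for a share under 0.05, so grouping by chance and genotype cannot be told apart by splits alone. Between the genotypes the true grouping was the only 1 of 10 splits to call as many genes at 10 DAP (78, highest other 7), 26 DAP (2552, other 20), 34 DAP (6507, other 0) and 42 DAP (5381, other 1). At 18 DAP 2 of 10 splits did, and the split of WT replicates 1 and 2 with clnor replicate 3 against the rest called 2629 genes against 387. This points to a structure of the samples other than the labelled genotype. An exchange of the labels of the replicate 3 libraries would give this same split. Within WT 1 of 10 splits, the true one, called as many genes in each of 7 age comparisons. Real counts were 5328 (highest other 17), 6774 (5), 8003 (0) and 8405 (1) against 10 DAP, 6093 (83) from 18 to 26 DAP, 5454 (3) from 26 to 34 DAP and 619 (2) from 34 to 42 DAP. Within clnor the true split also ranked highest in 6 comparisons: 1168 (highest other 922), 5748 (3), 3995 (167) and 6441 (1) against 10 DAP, 5196 (11) from 18 to 26 DAP and 2612 (10) from 26 to 34 DAP. From 34 to 42 DAP, 2 of 10 splits of clnor called as many genes, and clnor 34 DAP replicates 1 and 3 with 42 DAP replicate 2 against the rest called 880 genes against 338, again a structure other than age.

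With 100 relabellings of genotype within ages, counted with the true one, only 1 called as many genes averaged over ages (7958, highest other 5150) and for the change of the difference at 26 DAP (665, other 122), 34 DAP (3951, other 2406) and 42 DAP (3223, other 2366), and 2 did over the 4 later ages (3805, highest other 5062). At 18 DAP 16 of 100 called at least 5 genes (highest other 616), so grouping by chance is not excluded there.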

How the results depend on the processing

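In this part the runs with lists as first written, without the 5 libraries nearest to another group and without 26 DAP were chosen after seeing the data; all other alternatives were fixed before the data were examined. No list or named gene called in the main or the alternative run changed direction between them. Lists not called did, such as sugar metabolism (upward; downward with the 5 TPM filter, 0.981, and with the lists as first written, 0.986) and NAC (downward with the 5 TPM filter, 0.981). The side with more called genes also changed for some counts, as averaged from 65.9 to 47.6% higher after quantile normalization. Of the counts under settings other than leaving out single libraries, 266 stayed within 1.5 times the reported count, 21 were larger and 37 smaller. That tally includes the runs without the 5 libraries nearest to another group and without 26 DAP. The clnor against WT counts at 34 and 42 DAP and averaged, and those for the change of the difference at 34 and 42 DAP, stayed within that range when any single library was left out. Of 277 gene and contrast pairs named, 252 were called and 183 were called under every alternative that keeps all libraries. The ripening position difference stayed below 0 and past its threshold in all 34 runs. For the changes below the cause was not tested unless it is given.

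At 10 DAP the count was 31 with a pseudocount of 0.1, 125 without a filter and 44 with a filter at 5 TPM, and the interaction at 18 DAP called 18 without a filter. Scaling gave 154 at 10 DAP after quantile normalization, and for WT 42 against 34 DAP 404 (upper quartile) and 169 (quantile).

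A fold of at least 2 beside the threshold removes small changes by construction. It left 1384, 3402 and 2915 genes between genotypes at 26, 34 and 42 DAP and 1469 averaged. Against 10 DAP it left 2359, 3451, 4466 and 4676 in WT and 594, 2733, 1919 and 3176 in clnor. Between successive ages from 18 DAP it left 2803, 2424 and 274 in WT and 2324, 1238 and 218 in clnor.

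A limma fit of only the groups compared has fewer degrees of freedom and takes the spread from those groups alone. Fewer degrees of freedom alone do not account for counts of 0, since genotype comparisons at 26, 34 and 42 DAP have as few. In this fit 5 counts fell to 0. These were clnor against WT at 10 DAP (0; 1362 at unadjusted p under 0.05) and 18 DAP (0; 1377), the interaction at 18 DAP (0; 948), clnor 18 against 10 DAP (0; 2089) and clnor 42 against 34 DAP (0; 2618). In WT 2373 genes were called for 18 against 10 DAP, 3519 for 26 against 18 and 409 for 42 against 34 DAP. In clnor 3452, 1361 and 3893 were called at 26, 34 and 42 against 10 DAP and 1312 for 34 against 26 DAP.

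Replicate numbers did not pair the genotypes: of 15 pairs 4 correlated above 0.1 (range -0.407 to 0.247), and 5 matched best with their own number. A random replicate block within age (correlation -0.0767) gave 51 genes at 10 DAP and 244 at 18 DAP, and a fixed replicate block moved no count over 1.5 times.

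Array weights raised counts. Between genotypes they gave 720, 2925 and 6191 at 10, 18 and 26 DAP, for the interactions 506, 3124 and 5445 at 18, 26 and 42 DAP and 9341 over the later ages. They gave 9267 and 5093 for WT 34 against 26 and 42 against 34 DAP, and in clnor 4215 for 18 against 10 DAP and 7990, 6933 and 4152 between successive ages from 18 DAP.

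Of the lists averaged over ages, 15 not called by camera passed fry, a test of the members themselves and not against other genes. Upward were sugar transport (0.000127), gibberellin (0.000127), AP2/ERF (0.000127), auxin (0.000273), MADS-box (0.000273), abscisic acid (0.000348), WRKY (0.000383), ethylene (0.000504), phloem (0.00127), sugar metabolism (0.0245), cell cycle (0.0298), cell wall loosening (0.0363) and ribosomal protein (0.0363). Downward were seed markers (0.00884) and carotenoid synthesis (0.0253). With index genes only, the closest WT age was 10 for clnor 18 DAP replicate 1 and 26 for clnor 34 DAP replicate 2. With WT 42 DAP in place of 34 DAP as the end of the course, WT at 34 DAP lay at 0.919 instead of 1.

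Without the 5 libraries nearest to another group, counts were 207 at 10 DAP and 4202 at 18 DAP between genotypes, 1017 for the interaction at 18 DAP, 2661 for clnor 34 against 10 DAP, and 1610 and 1687 for 42 against 34 DAP in WT and clnor. Without 26 DAP no count moved over 1.5 times.

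Leaving out single libraries gave 13 to 309 genes at 10 DAP, 9 to 2196 at 18 DAP and 1488 to 2432 at 26 DAP between genotypes, and 3 to 266 and 330 to 889 for the interactions at 18 and 26 DAP. It gave 2819 to 6304 for WT 18 against 10, 110 to 604 for WT 42 against 34, 100 to 3455 for clnor 18 against 10, 1328 to 2253 for clnor 34 against 26 and 27 to 724 for clnor 42 against 34 DAP. The table keeps no depth, so how far depth limits low genes cannot be given.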

Other observations

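In this part the search for genes peaking at 26 DAP, the clock gene list and its count at 18 DAP were chosen after values were seen, and the genes named were singled out for that reason.

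Some genes peaked at 26 DAP in WT and clnor alike. Allene oxide cyclase (Cla97C03G060720), of jasmonate synthesis, stood at 4.06 ± 1.73, 129.5 ± 82.6 and 0.79 ± 0.259 TPM in WT at 18, 26 and 34 DAP and at 8.57 ± 6.08, 132.9 ± 71.2 and 3.68 ± 2.72 TPM in clnor. A lipoxygenase gene (Cla97C09G163060) was at 84.1 ± 23.6 TPM in WT and 134.1 ± 86.3 TPM in clnor at 26 DAP, WRKY53 (Cla97C07G141890) at 55.9 ± 32.4 and 75.7 ± 67.1 TPM, and a xyloglucan endotransglucosylase gene (Cla97C06G122630) at 1197 ± 399 and 1212 ± 584 TPM. In all 592 genes peaked in both genotypes (of 1663 in WT and 922 in clnor) and 256 dipped in both (32.7 by chance), with 1 gene opposite. Among the shared peaks were 9 of 43 cell wall synthesis genes (adjusted one-sided Fisher's exact p 0.00042) and 5 of 117 cell wall loosening genes (adjusted exact p 1). They also held 9 of 48 WRKY genes (0.000533), 8 of 53 NAC genes (0.00446) and 10 of 86 AP2/ERF genes (0.00599). These tests count genes of a list as independent, which they may not be, and the 26 DAP pattern was chosen after values were seen. Their p-values are therefore descriptive only. Shared dips included an aquaporin gene (Cla97C07G132470), at 2224, 252 and 851.2 TPM in WT at 18, 26 and 34 DAP and 2163, 212.7 and 548.5 TPM in clnor, and a chlorophyll a-b binding protein gene (Cla97C02G029240), at 448.3, 81.98 and 428.7 TPM in WT.

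Some genes of the circadian clock had other levels at 18 DAP than at the ages around it. LHY (Cla97C06G111640), a morning clock gene, was at 29.8, 313 and 15.2 TPM in WT at 10, 18 and 26 DAP and at 68.7, 256 and 10.6 TPM in clnor. LNK1 (Cla97C10G192390) was at 5.98, 55.6 and 7.35 TPM in WT and 21.8, 70.1 and 3.73 TPM in clnor, and the evening gene EARLY FLOWERING 4-like (Cla97C07G132630) at 50.8, 0.96 and 11.7 TPM in WT and 13, 0.84 and 16 TPM in clnor. Of 20 genes with a clock name, 8 (40%) differed at 18 DAP from both neighbouring ages in the same direction in both genotypes, against 1.39% of other genes. In WT alone it was 11 (55%, others 11.5%) and in clnor 8 (40%, others 2.14%). No p-value is given, since the genes and the age were chosen for this pattern. The labels give no hour of harvest, and the cause was not tested.

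The two-component response regulator-like gene APRR2 (Cla97C09G175170) was at 0.34, 9.12, 55, 14.8 and 18.8 TPM in WT from 10 to 42 DAP and at 0.33, 6.82, 1.95, 0.99 and 0.94 TPM in clnor. Another APRR2-like gene (Cla97C10G186530) was at 8.43, 20.24, 60.01, 30.66 and 65.65 TPM in WT and at 7.27, 20.73, 17.17, 26.85 and 48.53 TPM in clnor. Both entered the clock gene list by name, which does not show a role in the clock.

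WT levels also left the clnor range: 1064 genes in WT at 42 DAP lay above and 1347 below clnor at all 5 ages (14.6% of the genes tested). At 42 DAP the ripening position was 0.948 in WT and 0.485 in clnor, so a delay of clnor alone would also give such genes. In clnor at 34 DAP 414 genes lay above and 153 below WT at all ages (3.44%). The thionin-like protein 2 gene (Cla97C09G164380) reached 1955.97 TPM in 1 clnor library of 34 DAP, where the group mean was 653 ± 1130 TPM.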
